A study of Homo sapiens with 9 samples.

How the data were processed

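RNA was measured by poly-A RNA sequencing in 9 libraries of TYUC-1, which the labels describe as a neuroendocrine esophageal carcinoma cell line grown in suspension. The labels give 3 groups of 3 biological replicates, with cells taken on day 0, day 3 or day 6 of exposure to EPZ-6438, a small-molecule inhibitor of the histone methyltransferase EZH2. The labels' protocol names a dose of 2 uM EPZ-6438 or DMSO. All 9 libraries carry EPZ-6438 as their treatment, and whether the day 0 cells had received DMSO is not stated. No vehicle-treated library from day 3 or day 6 was among those analysed, so exposure to the inhibitor and days in culture cannot be separated in any comparison. RNA was extracted with TRIzol and libraries were made with a TruSeq poly-A kit, per the labels' protocols, and whether the counts used strand is not stated.

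The submitters' processing notes name bcl2fastq 2.19, kallisto 0.44.0 and DESeq2 (version not given), together with the builds GRCh38, GRCm38 and hg38, without saying what each was used for. The deposited table holds estimated counts for 35762 gene symbols in 9 columns. The values were whole numbers that had not been scaled to a common total, and how transcripts were summed to genes and made whole is not stated. Kallisto assigns reads that match several transcripts by estimation, so genes with near-identical copies (HLA, MAGE, SSX, PAGE, XAGE, SPRR, HSPA and histone genes, and genes with processed pseudogenes such as HSPD1, HSP90AA1 and the ribosomal protein genes) have uncertain counts. Counts of overlapping or antisense genes cannot be told apart without strand. Of the 35762 symbols, 33545 matched GENCODE release 29 by symbol and 34798 by symbol or gene ID. Coordinates are those of that release on GRCh38, 1-based.

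The deposited estimated counts were rounded to whole numbers, scaled with the TMM method and tested with the quasi-likelihood F-test of edgeR 4.0.16 under R 4.3.3. Genes were kept by filterByExpr (minimum count 10), which left 15345 genes. All 9 libraries entered 1 fit with a mean per day, so the 3 comparisons shared 1 estimate of the spread, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Levels are given in CPM, the count scaled by the TMM-scaled library size. Libraries held between 21638874 and 31235055 estimated counts, so 3 counts corresponded to 0.098 to 0.141 CPM, which is the upper limit a count of 0 allows in a library. For genes with few counts on a day, the counts of its 3 libraries were pooled and the ratio to another day was given with an exact 95% interval for 2 Poisson counts, divided by the pooled library sizes. Where the pooled count was 0, the fold is a lower bound against a floor of 3 counts over the group. These intervals and floors cover counting error only.

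Gene lists were tested with camera from limma 3.58.1 at its preset inter-gene correlation of 0.01, and Benjamini-Hochberg adjustment was made over the 38 lists with at least 3 tested members in each comparison. Of 39 lists fixed before the data were examined, the list of erythroid markers had no tested member. Each list was also tested with an estimated correlation and with fry, which asks whether the members move, on balance, one way. With an estimated correlation no list passed the threshold in any comparison, with lowest adjusted p of 0.244, 0.137 and 0.157 for day 3 against day 0, day 6 against day 0 and day 6 against day 3. At an unadjusted p under 0.05 it gave 7, 11 and 7 lists, and fry called 28, 32 and 25 lists. Counts of list members are given over all genes tested, and where they differed also adjusted over the list alone. List totals are tested members, for example 27 of 50 neuroendocrine genes in the table and 76 of 113 developmental transcription factors. Tested were also 15 of 30 gastric and intestinal, 16 of 30 cancer germline and 5 of 12 endothelial genes. A gene silent on day 0 was tested only if it was counted later, which favours rises. Of all genes tested 40.6%, 54.6% and 16.3% were called in the 3 comparisons.

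Genes were named by a rule fixed before the data were examined. It takes 19 genes of Polycomb, squamous, neuroendocrine, Notch and cell cycle function in every comparison, and the 8 largest rises and 8 largest falls among genes past the threshold with a mean of at least 5 CPM and no overlap between the libraries of the days compared. It also takes up to 4 members of each list with the lowest p, or up to 2 with the highest mean CPM where none passed. Any other gene is said to have been chosen after its values were seen.

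The alternatives were median-ratio size factors, library size only, no filter on low counts, a mean of at least 5 CPM, DESeq2 1.42.0, limma-voom, a fit of only the 2 days compared, the replicate number as a block, a minimum change of 2-fold, an adjusted p under 0.01, removal of mitochondrially encoded genes and the 20 most abundant genes before scaling, and each library left out in turn. Gene lists were tested again only with the estimated correlation, fry, median-ratio size factors, library size only, a mean of at least 5 CPM, the replicate block and each library left out, and with the trend named next. The lists of fibroblast and endothelial markers had fewer than 3 members with a mean of at least 5 CPM and were not tested there. Removal of a trend with GC content and transcript length was added after the data were seen. The procedure was tested on simulated data in which 200 genes were changed up or down at random and 1 further list was raised 1.5-fold. The data differ, with 40.6% and 54.6% of genes called against day 0 and large changes mostly upward. No simulated library stood apart as D0_2 did, so the shares that follow may not carry over. In simulations of day 3 against day 0 (14978 genes tested) 50.7% of genes changed 1.5-fold, 74.6% of those changed 2-fold and 92.4% of those changed 4-fold were recovered, with 8 unchanged genes called. For day 6 against day 0 (14964 genes) these shares were 55.2%, 82.1% and 97%, with 13 unchanged genes called. For day 6 against day 3 (14971 genes) they were 50.7%, 71.6% and 93.9%, with 10 unchanged genes called. Some genes that the rule for named genes covers are not reported here.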

Results

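TYUC-1 cells were sequenced before and during exposure to the EZH2 inhibitor EPZ-6438, with 3 libraries each on day 0, day 3 and day 6. EZH2 is the catalytic subunit of Polycomb repressive complex 2 (PRC2), which methylates histone H3 and is associated with repressed developmental genes. The series title names p63, the product of TP63 and a master regulator of squamous epithelium, and a change of cells between squamous and neuroendocrine states. The day 0 libraries held 31235055, 25979462 and 21638874 estimated counts. Those of day 3 held 26211243, 29589297 and 23072804, and those of day 6 held 29031066, 21844560 and 22784637. A library is written as its day and replicate (D0_2 is replicate 2 of day 0). Values are mean ± SD in CPM over n = 3 libraries, and log2 fold changes carry their standard error (SE). Adjusted p-values are from edgeR for genes and from camera for lists. Beside each list that passed stands its adjusted p with an estimated correlation. For each gene said to have risen or fallen, all 3 libraries of one day lay beyond all 3 of the other unless stated.

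**Figure D1:**
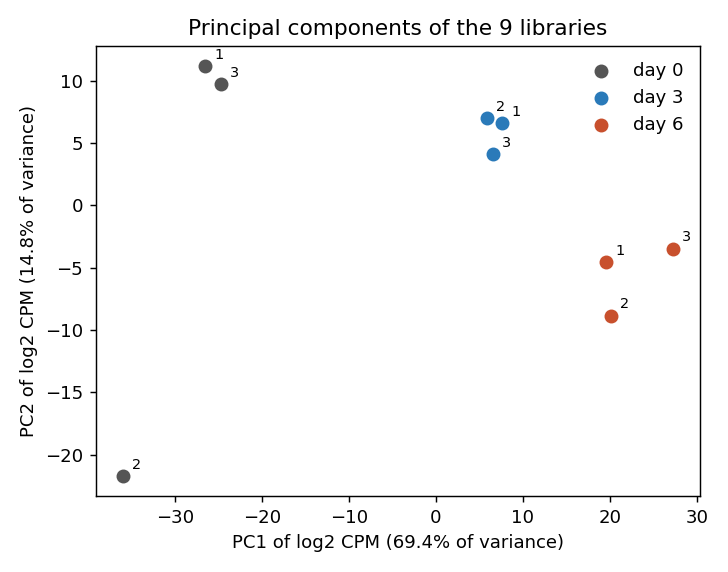
The 9 libraries by the first principal component (69.4% of the variance, horizontal) and the second (14.8%, vertical) of log2 CPM, coloured by day and numbered by replicate. The days follow each other along the first component, and replicate 2 of day 0 lies apart from the other day 0 libraries on the second.

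Libraries of the same day resembled each other most. Across 10203 genes the mean correlation of D0_2 with the other day 0 libraries was 0.974, against 0.948 with day 3 and 0.923 with day 6. This was the lowest mean correlation of the 9 libraries within their day. Mitochondrially encoded genes took 9.78% to 13.3% of the counts of each library. This list passed in no comparison (adjusted p = 0.398, 0.846 and 0.389 for day 3 against day 0, day 6 against day 0 and day 6 against day 3). Among its 13 members MT-ATP8 rose from 366 ± 36.5 on day 0 to 519 ± 94.8 on day 3 and 515 ± 60.6 on day 6.

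Transcripts of EZH2, SUZ12 and EED were lower on day 3 and on day 6 than on day 0, while the list of PRC2 subunits did not pass. EZH2 (chromosome 7, 148807383 to 148884321, minus strand) went from 193 ± 3.95 on day 0 to 167 ± 2.34 on day 3 and 150.3 ± 8.46 on day 6. The scaffold subunit SUZ12 went from 173 ± 17.6 to 131 ± 1.12 and 116 ± 7.0, and EED, which binds the methylated histone, from 42.2 ± 5.03 to 29.5 ± 0.813 and 28 ± 2.2. EZH1, the alternative catalytic subunit, was at 38.6 ± 3.9, 44 ± 1.08 and 41.6 ± 2.36 and did not pass the test in any comparison. Against day 0 its day 3 level did pass without D0_3 (adjusted p = 0.0414), among genes with a mean of at least 5 CPM (0.0451) and with a GC and length trend removed (0.0269), in a range up to 0.233. The log2 fold changes on day 6 were -0.36 for EZH2 (SE 0.07, adjusted p = 0.00083), -0.58 for SUZ12 (SE 0.08, adjusted p = 0.000128) and -0.59 for EED (SE 0.09, adjusted p = 0.000253). Transcript levels do not measure inhibition of the enzyme. The lower EZH2 level on day 3 (log2 fold change -0.21, SE 0.07, adjusted p = 0.0289) lost its call in 8 of 19 alternatives, which ranged from 0.00312 to 0.177. These were library size only, a mean of at least 5 CPM, the GC and length trend, and the fits without D0_1 (0.0574), D0_3 (0.0505), D3_1 (0.0889), D3_2 (0.0789) or D3_3 (0.0906).

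**Figure D2:**
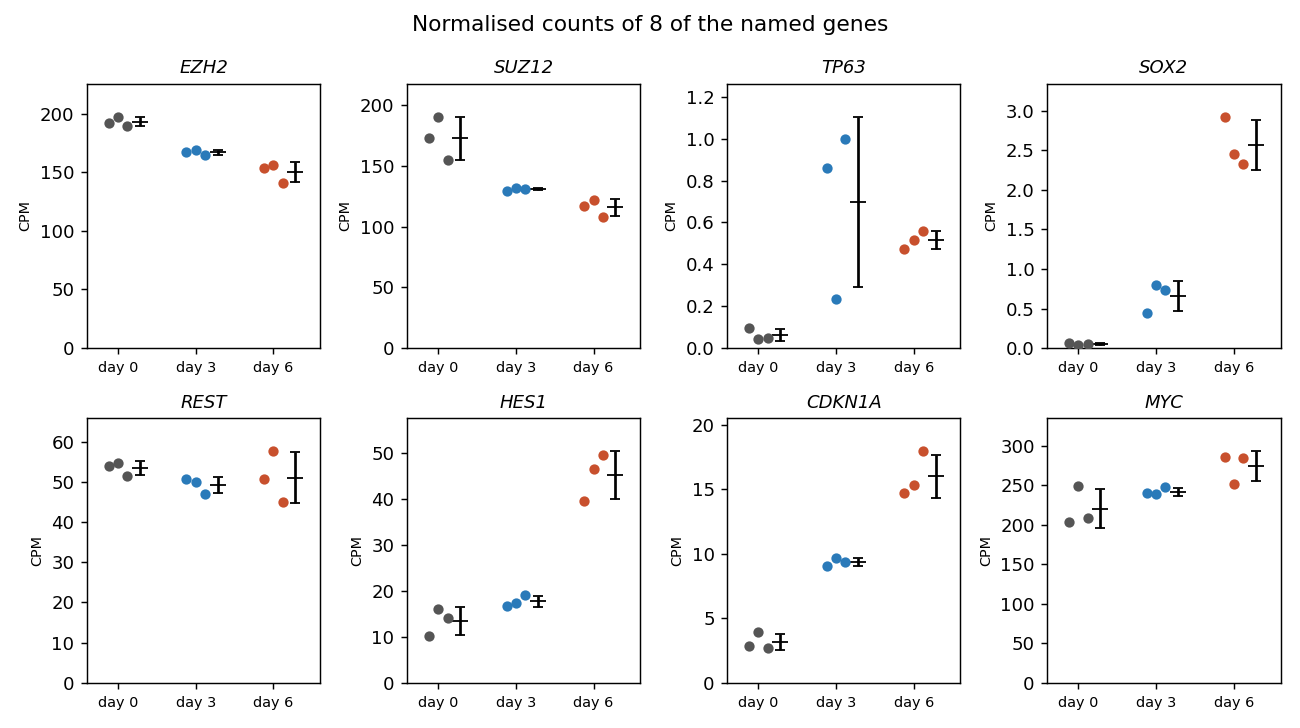
Level in CPM (vertical, linear from 0) on day 0, day 3 and day 6 for EZH2, SUZ12, TP63, SOX2, REST, HES1, CDKN1A and MYC. Each point is 1 library, and the bar beside the points is the mean with its SD over n = 3. SOX2 went from 0.0516 on day 0 to 2.57 on day 6.

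The comparison of day 3 with day 0 asks which transcripts had changed after the first 3 days of exposure. The 8 genes with the largest rises were close to undetected on day 0. The collagen genes COL6A1, COL6A2 and COL5A1 reached 9.33 ± 0.867, 2.49 ± 0.58 and 4.28 ± 1.09, and the calcium channel gene CACNA1H reached 5.97 ± 0.573. In pooled counts these were 39.3-fold (95% interval 24.7 to 66.7), 47.3-fold (18.2 to 175), 45.9-fold (22.1 to 115) and 64.5-fold (31 to 161) the day 0 level. The atypical cadherin gene FAT1 (6.2 ± 0.588), the kinesin gene KIF1A (3.25 ± 0.255), the ciliary gene EVC (2.46 ± 0.603) and FXYD5 (2.51 ± 0.198), a regulator of the sodium pump, were the other large rises.

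Among the largest falls on day 3, PLN, which encodes the calcium pump inhibitor phospholamban, went from 21.8 ± 4.89 to 9.46 ± 0.729 (log2 fold change -1.20, SE 0.14, adjusted p = 7.17e-05). NRCAM, a neuronal cell adhesion gene, went from 13 ± 0.886 to 5.8 ± 0.479 and RGS21, a regulator of G protein signalling, from 7.59 ± 0.755 to 2.8 ± 0.952. HSPD1, the mitochondrial chaperonin, went from 1199 ± 72.5 to 634 ± 26.8, and GFM1, a mitochondrial translation factor, from 177 ± 8.48 to 95.2 ± 0.415. SPRR1A, CDIN1 and DERPC completed this group, with log2 fold changes of -1.24, -1.19 and -1.32. DERPC shares its locus with CHTF8 and its count is uncertain. In all, 3445 genes were higher and 2780 lower on day 3, of 15345 tested. At least 2-fold changes made up 1408 of the higher and 59 of the lower genes. The libraries of both days did not overlap for 6131 of the 6225 called genes and for 53.8% of all genes, against the 10% that chance gives for 3 against 3. With library size as the only scaling 69.2% of the called genes were higher, against 55.3%, and without D3_1 the genes called lower in D3 vs D0 numbered 1846. Among genes with a mean of at least 5 CPM only 44.5% of the called genes were higher, so there the balance of all calls turned.

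Lineage genes moved in both directions by day 3. TP63 (chromosome 3, 189631416 to 189897279, plus strand) had 5 counts over the day 0 libraries and 53 over the day 3 libraries, a ratio of 10 (95% interval 4.04 to 32.1, adjusted p = 0.00206), at a level of 0.697 ± 0.407. SOX2, a transcription factor of stem and foregut cells (chromosome 3, 181711924 to 181714436, plus strand), had 4 and 53 counts, a ratio of 12.5 (4.62 to 47.7, adjusted p = 0.000125). KRT5, a basal keratin gene (chromosome 12, 52514575 to 52520687, minus strand), fell from 1.05 ± 0.0999 to 0.417 ± 0.175 (log2 fold change -1.36, SE 0.30, adjusted p = 0.00362).

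Of 23 tested basal squamous genes 14 rose and 2 fell on day 3 (17 and 2 adjusted over the list alone). The cadherin gene CDH3 went from 5.81 ± 0.428 to 23.4 ± 1.11, GPC1 from 13 ± 1.65 to 34.5 ± 1.03, TRIM29 from 49.4 ± 1.51 to 87.5 ± 2.7 and the hemidesmosome integrin ITGB4 from 4.39 ± 0.675 to 12.4 ± 1.48. The list was higher (camera, adjusted p = 0.000747, and adjusted p = 0.244 with an estimated correlation). KRT14, another basal keratin gene, had a mean of 0.0109 ± 0.0189 on day 0 and was at 0 on day 3. The squamous differentiation list did not pass (camera, adjusted p = 0.357), with 5 members higher and 7 lower of 23. The plakin gene PPL (8.54 ± 1.76 to 27.4 ± 0.565), the suprabasal keratin KRT13 (10.3 ± 0.653 to 18.3 ± 1.19) and CNFN (3.17 ± 0.606 to 6.67 ± 0.296) rose, and the cornified envelope gene SPRR1B fell from 2.42 ± 0.604 to 0.646 ± 0.0808.

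Of 27 tested neuroendocrine genes, from a list of 50, 14 rose and 2 fell on day 3. The list was higher (camera, adjusted p = 0.049, and adjusted p = 0.244 with an estimated correlation). Its risers include KIF1A and the adhesion gene NCAM1 (6.25 ± 0.761 to 15.4 ± 0.426). KIF5C, a neuronal kinesin gene, had 1 count on day 0 and 32 on day 3 (ratio 30.3, 5.06 to 1230). NEUROD1 (3.06 ± 0.58 and 2.71 ± 0.372), INSM1 (4.41 ± 0.181 and 4.07 ± 0.52), SYP (5.85 ± 0.948 and 4.79 ± 0.152) and the neuronal repressor REST (53.4 ± 1.69 and 49.2 ± 2.07) did not pass. Without D0_2 the lower level of SYP passed (adjusted p = 0.0164), in a range of 0.0149 to 0.395, and with the GC and length trend removed those of SYP and INSM1 (0.017) did. CHGA and CDKN2A were listed at 0 in all 9 libraries, which allows at most 0.141 CPM in the shallowest library.

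Signalling genes rose as groups on day 3. In the WNT list 16 of 22 members rose and none fell (17 and 0 adjusted over the list alone). Among them were the feedback inhibitors NKD1 (0.269 ± 0.111 to 3.88 ± 0.481) and NKD2 (9.04 ± 0.586 to 18.1 ± 1.2) and the receptor genes FZD8 (1.38 ± 0.124 to 5.19 ± 0.865) and FZD7 (6.5 ± 0.407 to 12.3 ± 0.471). The list passed (camera, adjusted p = 2.83e-06, and adjusted p = 0.244 with an estimated correlation). In the TGF-beta and BMP list 17 of 27 rose and 2 fell (18 and 3 adjusted over the list alone). TGFB1 went from 39.5 ± 2.77 to 77.4 ± 6.77, and the antagonists GREM1 (0.405 ± 0.2 to 4.09 ± 0.565) and CHRD (0.202 ± 0.132 to 2.82 ± 0.607) and the ligand gene BMP6 (0.872 ± 0.143 to 2.28 ± 0.0257) rose. It passed (camera, adjusted p = 0.000747, and adjusted p = 0.244 with an estimated correlation). Of 76 developmental transcription factors 48 rose and 4 fell, led by PAX9 (0.44 ± 0.134 to 3.52 ± 0.382), NKX3-2, DLX4 and DLX3. Their median log2 fold change was 0.58, or 0.56 with 4 genes at 0 on day 0 set to their bound (camera, adjusted p = 2.83e-06, and adjusted p = 0.244 with an estimated correlation).

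Of 23 Notch genes 11 were higher and none lower (camera, adjusted p = 0.049, and adjusted p = 0.244 with an estimated correlation). They include HEYL (1.83 ± 0.261 to 4.86 ± 0.0344), NOTCH3 (1.78 ± 0.114 to 3.5 ± 0.333), MAML2 and the ligand gene DLL4. NOTCH1 (1.15 ± 0.936 and 2.07 ± 0.441) did not pass, but did without D0_1 (adjusted p = 0.0146, in a range up to 0.428). The target gene HES1 (13.4 ± 3.06 to 17.8 ± 1.18, adjusted p = 0.0472) lost its call in 11 of 19 alternatives, which ranged from 0.00363 to 0.153. These were median-ratio scaling, the removal of dominant genes, a fit of only the 2 days, and the fits without any library other than D0_2 (0.0557 to 0.153). Of 17 YAP targets and pathway genes 8 rose and 1 fell (camera, adjusted p = 0.049, and adjusted p = 0.244 with an estimated correlation). TEAD2, AJUBA and WWTR1 were among the risers. YAP1 itself had no counts on day 0 and 43 on day 3 and was at least 13.6-fold higher. The Hedgehog list had 4 of 10 higher (HHIP, CDON, GAS1 and SMO) and none lower. It passed (camera, adjusted p = 0.0478, and adjusted p = 0.261 with an estimated correlation).

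Genes of DNA synthesis fell. Of 43 replication genes 18 fell and 1 rose (19 and 1 adjusted over the list alone). The ribonucleotide reductase gene RRM2 went from 352 ± 25.9 to 237 ± 10.4 and the origin licensing gene CDC6 from 131 ± 7.46 to 89.8 ± 5.48. CHAF1B went from 92.2 ± 4.15 to 72.4 ± 2.35 and the polymerase gene POLA1 from 114 ± 4.64 to 85.7 ± 1.9. As a list they were lower (camera, adjusted p = 0.000447, and adjusted p = 0.261 with an estimated correlation). Of 43 mitosis genes 8 fell, among them KIF20B, BUB3, BUB1B and CENPN, and 1 rose (7 and 0 adjusted over the list alone). Their list was lower (camera, adjusted p = 0.049, and adjusted p = 0.602 with an estimated correlation). The cell cycle inhibitor genes CDKN1A (3.17 ± 0.646 to 9.35 ± 0.289) and CDKN1C (2.61 ± 0.205 to 8.84 ± 1.21) rose, and CDKN2D rose from 6.19 ± 1.25 to 8.34 ± 0.707 with overlapping libraries. The list of 5 tested CDK inhibitors did not pass (camera, adjusted p = 0.156). Heat shock genes fell, 10 of 15 with 1 higher (11 and 1 adjusted over the list alone). They include HSP90AA1 (3085 ± 247 to 1837 ± 53), DNAJA1 (808 ± 78.8 to 467 ± 25.6) and HSPH1 (382 ± 34.1 to 210.3 ± 11.2). The list passed (camera, adjusted p = 0.000447, and adjusted p = 0.26 with an estimated correlation).

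Cholesterol synthesis genes rose, 13 of 24 with none lower (14 and 0 adjusted over the list alone). They include MVD (87.2 ± 6.94 to 142 ± 4.29), TM7SF2 and DHCR7, and the list passed (camera, adjusted p = 0.00898, and adjusted p = 0.293 with an estimated correlation). Of 17 genes of MHC class I presentation 9 rose and none fell (camera, adjusted p = 0.0303, and adjusted p = 0.293 with an estimated correlation). HLA-E went from 18.2 ± 0.943 to 31.2 ± 0.916, the peptide transporter TAP1 from 11.6 ± 0.116 to 18.1 ± 0.27 and the regulator NLRC5 from 7.1 ± 1.62 to 14.7 ± 0.645. HLA genes share sequence and their separate counts are uncertain. The interferon response list did not pass (camera, adjusted p = 0.0685), with 11 of 38 members higher and 3 lower (9 and 2 adjusted over the list alone). Among the higher were IFITM1 (1.71 ± 0.624 to 6.5 ± 0.194) and UBE2L6 (2.83 ± 1.02 to 10.3 ± 2.09). Cancer germline antigen genes, many with close copies in the genome, rose in 9 of 16 cases and fell in 3. MAGEC1 went from 1.36 ± 0.043 to 7.21 ± 0.176 and MAGEA10 from 1.05 ± 0.138 to 5.71 ± 0.517. As a list they were higher (camera, adjusted p = 0.0338, and adjusted p = 0.293 with an estimated correlation).

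Further lists passed on day 3. Of 24 mesenchymal genes 11 rose and 4 fell (adjusted p = 0.049, and adjusted p = 0.244 with an estimated correlation), with CAVIN1 from 9.48 ± 0.945 to 28.1 ± 1.32 and TGFBI from 3.25 ± 0.133 to 10.3 ± 0.769. Of 29 simple epithelial genes 13 rose and 1 fell (13 and 2 adjusted over the list alone), with the tight junction gene TJP3 from 19.6 ± 1.5 to 42.7 ± 0.5 (adjusted p = 0.049, and adjusted p = 0.407 with an estimated correlation). Of 15 gastric and intestinal genes 6 rose and 1 fell (adjusted p = 0.049, and adjusted p = 0.26 with an estimated correlation). The gastric mucin MUC5AC went from 0.571 ± 0.214 to 3.95 ± 0.519 and the secretory gene AGR2 fell from 3.88 ± 1.04 to 1.11 ± 0.403. In the glycolysis and hypoxia list 11 of 30 rose and 1 fell (adjusted p = 0.049, and adjusted p = 0.696 with an estimated correlation). Immediate early genes rose in 9 of 19 cases and fell in 1 (adjusted p = 0.0478, and adjusted p = 0.293 with an estimated correlation).

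Of the 21 lists called on day 3, 6 kept their call in all alternatives run for lists other than the estimated correlation (basal squamous, developmental transcription factors, DNA replication, WNT, cholesterol synthesis and heat shock). Several of the others lost it without single libraries. The neuroendocrine list did so without D0_1, D0_2, D0_3, D3_1, D6_1 or D6_2 (adjusted p up to 0.0721), the Notch pathway list without D0_2, D0_3, D3_1, D3_2 or D6_2 (up to 0.0959) and the YAP targets list without any but D0_1 and D6_3 (up to 0.0943). The simple epithelial list (up to 0.097) and the glycolysis and hypoxia list (up to 0.3) did so without any but D0_2, D6_1 and D6_3. The mesenchymal list did so without D0_1, D0_3, D3_1, D3_2 or D6_2 (up to 0.0647) and the gastric and intestinal list without D0_1, D0_2, D0_3, D3_1, D6_1 or D6_2 (up to 0.109). The mitosis list did so without D0_2, D3_1 or D6_2 (up to 0.273) and the immediate early list without D0_1, D0_3, D3_1 or D3_2 (up to 0.082). With the GC and length trend removed these lists other than the mesenchymal lost their call, as did the MHC class I presentation (0.0556) and Hedgehog pathway (0.0556) lists, and the median of the mitosis list was -0.001. Among genes with a mean of at least 5 CPM the TGF-beta and BMP pathway (0.116) and cancer germline antigens (0.344) lists lost theirs. So did the neuroendocrine, Notch pathway, mesenchymal, gastric and intestinal, mitosis and immediate early lists. With library size only the cancer germline antigens (0.052) and Hedgehog pathway (0.0571) lists did. The neuroendocrine, YAP targets, mesenchymal, gastric and intestinal, and mitosis lists were lost there too. With fry the mitosis (adjusted p = 0.223) and glycolysis and hypoxia (0.0585) lists were not called.

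**Figure D3:**
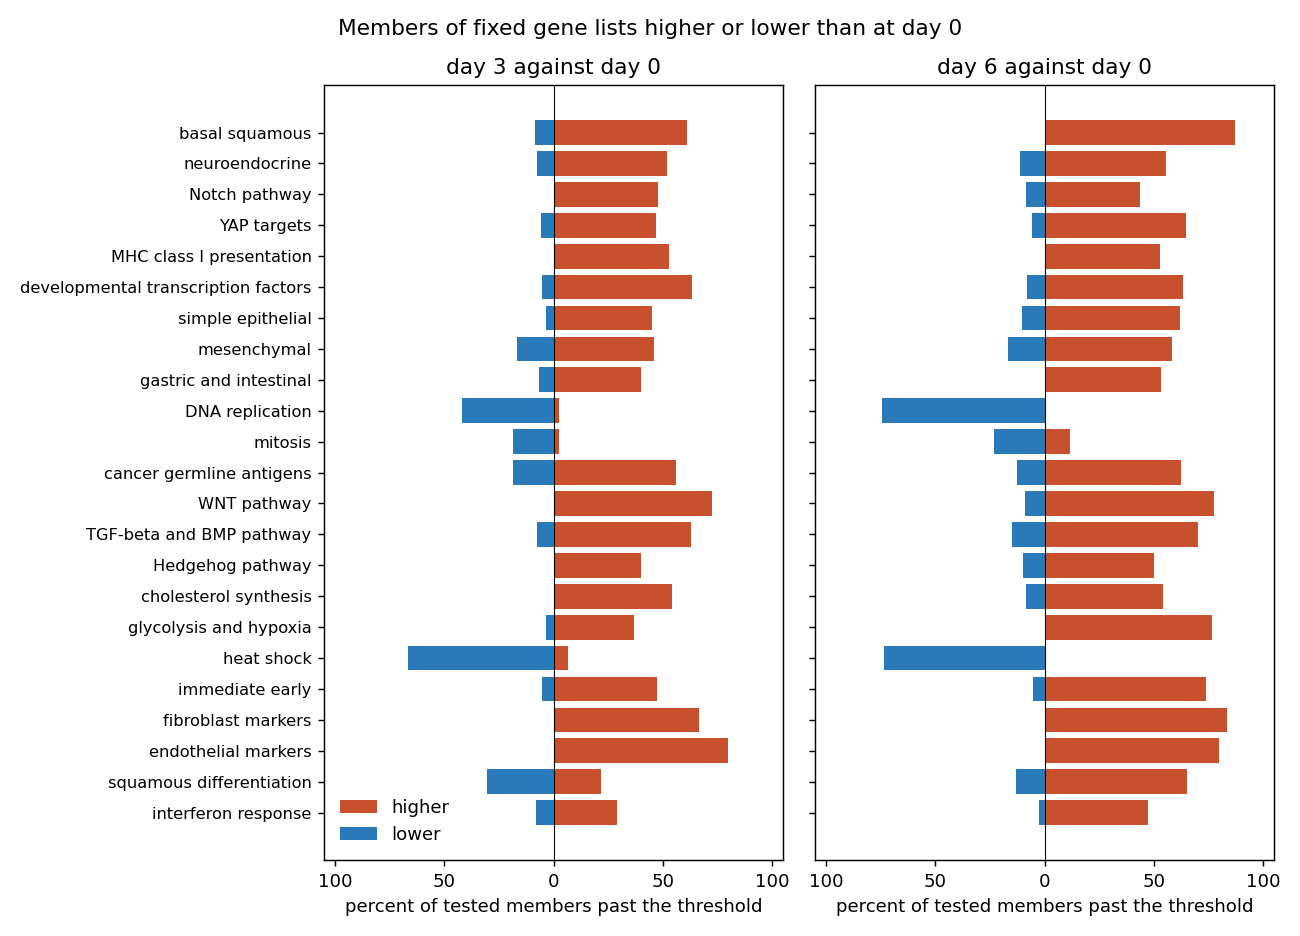
Percent of the tested members of each gene list that were higher (right of 0) or lower (left of 0) than on day 0 past the adjusted p threshold, on day 3 (left panel) and day 6 (right panel), for lists called in either comparison. On day 6, 20 of 23 basal squamous genes were higher and 32 of 43 replication genes lower.

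Against day 0, day 6 shows the state after the longest exposure. Of the 8 genes with the largest rises 7 were those named for day 3, and their levels had risen further. COL6A1 reached 37.9 ± 4.96, COL5A1 24.1 ± 2.2, KIF1A 26.8 ± 3.4, FXYD5 20.3 ± 2.55, CACNA1H 18.5 ± 1.57, COL6A2 18.1 ± 1.44, EVC 15.1 ± 0.0798 and DPYSL3, a neuronal cytoskeleton gene, 13.4 ± 1.02. In pooled counts COL6A2 was 338-fold (95% interval 132 to 1240) and KIF1A 286-fold (139 to 713) the day 0 level, and COL6A1 was 158-fold (99.9 to 267). SOX2 reached 2.57 ± 0.316, with 198 counts against 4 (ratio 49, 18.8 to 182).

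The largest falls on day 6 include that of PLN (21.8 ± 4.89 to 3.73 ± 0.0945, log2 fold change -2.55, SE 0.16, adjusted p = 1.2e-07). CALML3, a calmodulin-like gene of squamous epithelium, went from 10.4 ± 1.04 to 1.98 ± 0.13 and COL6A6 from 28.9 ± 7.71 to 6.58 ± 0.366. The others were DERPC, INSYN2A (12.4 ± 0.297 to 3.38 ± 0.318), the amino acid transporter SLC38A4, the G protein subunit GNG11 and ID3, an inhibitor of basic helix-loop-helix factors (12.8 ± 1.94 to 4.5 ± 0.213). In all, 4442 genes were higher and 3938 lower on day 6. Of these 2289 and 119 had changed at least 2-fold. The libraries did not overlap for 8070 of the 8380 called genes and for 58.7% of all genes, against 10% by chance. With library size as the only scaling 66.6% of the called genes were higher, against 53%, and the median of all genes shifted to 0.13 on the log2 scale. Among genes with a mean of at least 5 CPM only 39.8% of the called genes were higher, so there the balance of all calls turned.

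Squamous genes were higher on day 6. Of 23 basal squamous genes 20 rose and none fell (21 and 1 adjusted over the list alone), with a median log2 fold change of 1.24 (camera, adjusted p = 3.39e-06, and adjusted p = 0.137 with an estimated correlation). CDH3 reached 42.3 ± 3.18, GPC1 62 ± 7.49 and TRIM29 117 ± 10.7. The nerve growth factor receptor gene NGFR had no counts on day 0 and was at least 75.9-fold higher, and KRT5 reached 6.16 ± 0.852 (log2 fold change 2.55, SE 0.23, adjusted p = 2.25e-06). TP63 had 39 counts against 5 (ratio 7.72, 3.04 to 25.1, adjusted p = 0.00344) and was at 0.516 ± 0.0445. KRT14 stayed at 0.0256 ± 0.0226. In the squamous differentiation list 15 of 23 rose and 3 fell (camera, adjusted p = 0.00632, and adjusted p = 0.166 with an estimated correlation). The keratin gene KRT4 went from 0.65 ± 0.305 to 9.23 ± 1.47, the membrane protein gene EMP1 from 1.32 ± 0.291 to 7.27 ± 0.368, and PPL reached 36.9 ± 3.96.

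The neuroendocrine list held members that moved apart on day 6, with 15 higher and 3 lower of 27 (camera, adjusted p = 0.0229, and adjusted p = 0.137 with an estimated correlation). NCAM1 rose to 20.1 ± 1.12 and FOXA2, an endodermal transcription factor, was at least 52.1-fold higher with 158 counts against none. INSM1 (5.32 ± 0.404), SYP (6.07 ± 0.462), NEUROD1 (2.75 ± 0.838) and REST (51.1 ± 6.34) did not differ from day 0 past the threshold. HES1, a Notch target that encodes a transcriptional repressor, rose to 45.2 ± 5.12 (log2 fold change 1.76, SE 0.15, adjusted p = 1.71e-06). The Notch list had 10 of 23 higher and 2 lower (camera, adjusted p = 0.0281, and adjusted p = 0.137 with an estimated correlation). HEYL was at 7.14 ± 0.212, the coactivator gene MAML2 at 2.9 ± 0.256 and the fringe gene MFNG at 10.1 ± 0.6. NOTCH1 was at 1.69 ± 0.339 and did not pass, but did without D0_1 (adjusted p = 0.0262, in a range up to 0.918). MYC, from 220.2 ± 24.9 to 274 ± 19, had a log2 fold change of 0.31 (SE 0.09, adjusted p = 0.0107) and lost its call without D6_1 (0.0569), without D6_3 (0.0508) and with the GC and length trend removed (0.489), in a range from 1e-04.

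Replication genes were lower on day 6, 32 of 43 with none higher (35 and 0 adjusted over the list alone). RRM2 was at 189 ± 5.65, CDC6 at 72.9 ± 4.07, CHAF1B at 56.8 ± 1.06 and POLA1 at 69.2 ± 6.93, and the list passed (camera, adjusted p = 4.78e-08, and adjusted p = 0.137 with an estimated correlation). The mitosis list did not pass (camera, adjusted p = 0.224), with 5 higher and 10 lower of 43 (4 and 10 adjusted over the list alone). The phosphatase gene CDC25C (29.4 ± 3.55 to 41.6 ± 0.89) and the kinesin gene KIF2C rose and the kinase genes BUB1B and AURKA (107 ± 12.7 to 80 ± 2.46) fell. CDKN1A reached 16 ± 1.7 (log2 fold change 2.33, SE 0.14, adjusted p = 9.42e-08) and CDKN1C 10.8 ± 1.81. CDKN2C fell from 42.4 ± 3.78 to 31.3 ± 1.55, and the list of CDK inhibitors did not pass (camera, adjusted p = 0.404). Of 21 p53 targets 10 rose and 5 fell (camera, adjusted p = 0.224), with BBC3, which encodes the death-promoting protein PUMA, from 3.29 ± 0.117 to 18.3 ± 1.26. Of 15 genes of the BCL2 family 6 rose and 2 fell (camera, adjusted p = 0.533), with BOK, HRK and BCL2 rising beside BBC3.

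Genes of glycolysis and hypoxia rose, 23 of 30 with none lower (camera, adjusted p = 8.01e-05, and adjusted p = 0.401 with an estimated correlation). They include the glucose transporter SLC2A3 (0.433 ± 0.178 to 13.5 ± 1.91), NDRG1 (52 ± 10.9 to 389 ± 54.4), ALDOC (49.8 ± 10.9 to 143 ± 17.2) and SLC16A3. Heat shock genes were lower, 11 of 15 with none higher (camera, adjusted p = 8.26e-05, and adjusted p = 0.197 with an estimated correlation), with HSPD1 at 555 ± 56.9. In the unfolded protein and ATF4 list 10 rose and 9 fell of 26 (camera, adjusted p = 0.93). The amino acid response genes TRIB3, PHGDH and ASNS rose and the chaperone HSPA5 fell from 362 ± 20.4 to 247 ± 7.29. The cholesterol synthesis list did not pass on day 6 (camera, adjusted p = 0.0523), with 13 higher and 2 lower of 24.

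Antigen presentation and interferon genes rose on day 6. The MHC class I list had 9 of 17 higher and none lower (camera, adjusted p = 0.0133, and adjusted p = 0.223 with an estimated correlation). HLA-B was at 195 ± 14.7 from 102 ± 9.01, HLA-E at 45.1 ± 5.01 and TAP1 at 24.5 ± 2.06. The interferon response list had 18 of 38 higher and 1 lower (camera, adjusted p = 0.0166, and adjusted p = 0.137 with an estimated correlation). IFITM1 was at 9.39 ± 1.13, UBE2L6 at 16.5 ± 1.36, CMPK2 at 2.6 ± 0.152 and HERC6 at 15.5 ± 0.524. MHC class II genes did not pass as a list (camera, adjusted p = 0.1), with 4 of 9 higher (5 adjusted over the list alone), HLA-DPB1 among them with 90 counts against 10. The innate sensing list did not pass (camera, adjusted p = 0.819), with 4 higher and 3 lower of 10. NLRP1 (0.171 ± 0.0808 to 5.43 ± 0.802), CASP4 and STING1 (2.83 ± 0.797 to 9.47 ± 1.22) rose and the DNA sensor gene CGAS (26.5 ± 2.59 to 16.9 ± 1.06) fell. The NF-kB target list did not pass (camera, adjusted p = 0.0521), with 7 of 10 higher and 2 lower and the cytokine gene LIF from 0.697 ± 0.192 to 12 ± 0.568.

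Developmental transcription factors were higher on day 6 than on day 0 as a list. Of 76 members 48 rose and 6 fell (camera, adjusted p = 1.72e-05, and adjusted p = 0.137 with an estimated correlation). PAX9 was at 7.07 ± 0.11, DLX4 at 11.2 ± 0.777, DLX3 at 4.6 ± 0.306 and WT1 at 290 counts against 1 (ratio 287, 51.1 to 11400). HOX genes did not pass as a list (camera, adjusted p = 0.93), with 10 higher and 8 lower of 36. HOXB9 had no counts on day 0 and 154 on day 6 and was at least 50.8-fold higher, and HOXC12 rose from 14.8 ± 0.808 to 26 ± 1.69, while HOXC5 (36.2 ± 2.67 to 23.9 ± 1.73) and HOXA4 fell. The WNT list had 17 higher and 2 lower of 22 (18 and 2 adjusted over the list alone), with NKD1 at 12.7 ± 0.577 and FZD8 at 19.8 ± 2.67. It passed (camera, adjusted p = 5.35e-05, and adjusted p = 0.137 with an estimated correlation). The TGF-beta and BMP list had 19 higher and 4 lower of 27 (camera, adjusted p = 0.000792, and adjusted p = 0.152 with an estimated correlation). TGFB1 was at 97.2 ± 11.8 and the activin subunit gene INHBB at 733 counts against 2 (ratio 363, 100 to 3000). The Hedgehog list did not pass on day 6 (camera, adjusted p = 0.142), with 5 higher and 1 lower of 10.

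Genes of other epithelial and mesenchymal states rose too. The mesenchymal list had 14 higher and 4 lower of 24 (camera, adjusted p = 0.017, and adjusted p = 0.137 with an estimated correlation). TGFBI was at 36.3 ± 2.3, LGALS1 at 13.5 ± 0.21 from 1.35 ± 0.292 and ITGA5 at 41.6 ± 6.78 from 10 ± 0.699. The simple epithelial list had 18 higher and 3 lower of 29 (19 and 4 adjusted over the list alone), with the claudin gene CLDN4 from 40.2 ± 2.46 to 123 ± 12.3. It passed (camera, adjusted p = 0.0144, and adjusted p = 0.336 with an estimated correlation). The gastric and intestinal list had 8 of 15 higher and none lower (camera, adjusted p = 0.0138, and adjusted p = 0.137 with an estimated correlation). MUC5AC was at 8.5 ± 1.82, and CDX2 and GATA4, with no counts on day 0, were at least 15.5-fold and 48.8-fold higher. The YAP list had 11 higher and 1 lower of 17 (camera, adjusted p = 0.0229, and adjusted p = 0.137 with an estimated correlation), with YAP1 at 4.46 ± 0.95 and at least 110-fold higher. Cancer germline antigens had 10 higher and 2 lower of 16 (10 and 3 adjusted over the list alone) and passed (camera, adjusted p = 0.0059, and adjusted p = 0.197 with an estimated correlation). Immediate early genes had 14 higher and 1 lower of 19 (camera, adjusted p = 0.0133, and adjusted p = 0.222 with an estimated correlation), with IER3 from 12.8 ± 2.95 to 35.7 ± 4.57 and FOS from 13 ± 2.86 to 28.5 ± 3.43.

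Of the 20 lists called on day 6, 9 kept their call in all alternatives run for them other than the estimated correlation (basal squamous, MHC class I, interferon response, developmental transcription factors, DNA replication, WNT, glycolysis and hypoxia, heat shock and, in 1 alternative fewer, endothelial markers). Without D0_2 the Notch pathway (0.0585), YAP targets (0.0582) and fibroblast markers (0.0585) lists lost their call. With the GC and length trend removed the neuroendocrine (0.0685), Notch pathway, YAP targets, simple epithelial and immediate early lists did, up to 0.187. Among genes with a mean of at least 5 CPM the squamous differentiation, neuroendocrine, Notch pathway, mesenchymal, gastric and intestinal, cancer germline antigens and TGF-beta and BMP pathway lists did, from 0.0596 to 0.808.

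Markers of other cell types were measured beside these groups. Of 6 tested fibroblast markers 4 rose by day 3 and 5 by day 6 (camera, adjusted p = 0.0265 and 0.0173, and adjusted p = 0.26 and 0.222 with an estimated correlation). The matrix gene FBLN1 went from 0.731 ± 0.228 on day 0 to 22.7 ± 2.33 on day 6 and COL1A1 from 0.492 ± 0.145 to 9.53 ± 1.06. Of 5 endothelial markers 4 rose by both days (camera, adjusted p = 0.0338 and 0.0224, and adjusted p = 0.307 and 0.31 with an estimated correlation). EGFL7 went from 9.71 ± 1.36 to 24.1 ± 2.15 and TEK from 2.06 ± 0.461 to 9.39 ± 1.58 on day 6. The day 3 call of the endothelial markers was lost without D0_3 (0.0721) and without D6_2 (0.0637), and the calls of the fibroblast markers without D0_2 (0.0668 on day 3 and 0.0585 on day 6). The leukocyte list did not pass on either day (camera, adjusted p = 0.996 and 0.887). Of its 8 tested members 2 rose and 1 fell on day 3 (1 and 1 adjusted over the list alone), and 3 rose and 2 fell on day 6. Its members LYZ and LCP1 were at 544 ± 82.3 and 479 ± 18.7 on day 0 and 323 ± 2.52 and 368 ± 2.75 on day 6. By day 6 CORO1A rose from 12.1 ± 0.379 to 18.9 ± 2.23 and ITGB2 from 0.818 ± 0.173 to 2.77 ± 0.432. SLC4A1 of the erythroid list was at 0.335 ± 0.0447, 0.262 ± 0.0639 and 0.328 ± 0.0652 CPM on day 0, day 3 and day 6 and was not tested.

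The subunits of both Polycomb complexes were compared as lists. The PRC2 list did not pass on day 3 or day 6 (camera, adjusted p = 0.162 and 0.156), with 7 of its 13 members lower on each day. There 1 rose on day 3 and 2 on day 6 (3 and 2 adjusted over the list alone). AEBP2 fell from 192 ± 10.6 to 148 ± 2.86 and 118 ± 8.86, and PHF1 rose from 11.5 ± 0.804 to 16.1 ± 1.85 and 19 ± 0.912. The PRC1 list did not pass either (camera, adjusted p = 0.991 and 0.819), with 3 higher and 3 lower of 19 on day 3 and 3 higher and 5 lower on day 6. CBX7 rose from 13 ± 1.15 to 22.5 ± 1.74 and 27.7 ± 1.57 and PCGF6 fell from 13.9 ± 2.34 to 8.83 ± 0.268 and 8.98 ± 0.56.

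The comparison of day 6 with day 3 asks what changed during the second 3 days. Squamous genes rose as groups. KRT4 went from 0.272 ± 0.0475 on day 3 to 9.23 ± 1.47, SPRR1B from 0.646 ± 0.0808 to 7.77 ± 1.09, EMP1 from 0.968 ± 0.225 to 7.27 ± 0.368 and KRT5 from 0.417 ± 0.175 to 6.16 ± 0.852. The log2 fold changes were 5.04 for KRT4 (SE 0.35, adjusted p = 5.81e-07), 3.59 for SPRR1B (SE 0.24, adjusted p = 1.05e-06), 2.92 for EMP1 (SE 0.20, adjusted p = 2.14e-06) and 3.91 for KRT5 (SE 0.28, adjusted p = 1.41e-06). In the squamous differentiation list 13 of 23 rose and 1, CALML3, fell (camera, adjusted p = 9.11e-06, and adjusted p = 0.157 with an estimated correlation). In the basal squamous list 12 of 23 rose and 1 fell (14 and 1 adjusted over the list alone), including KRT17 (5.67 ± 0.365 to 11 ± 0.805) and S100A2 (3.47 ± 0.154 to 7.7 ± 0.327). That list passed (camera, adjusted p = 4.99e-06, and adjusted p = 0.157 with an estimated correlation). SPRR genes have close copies and their counts are uncertain.

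**Figure D4:**
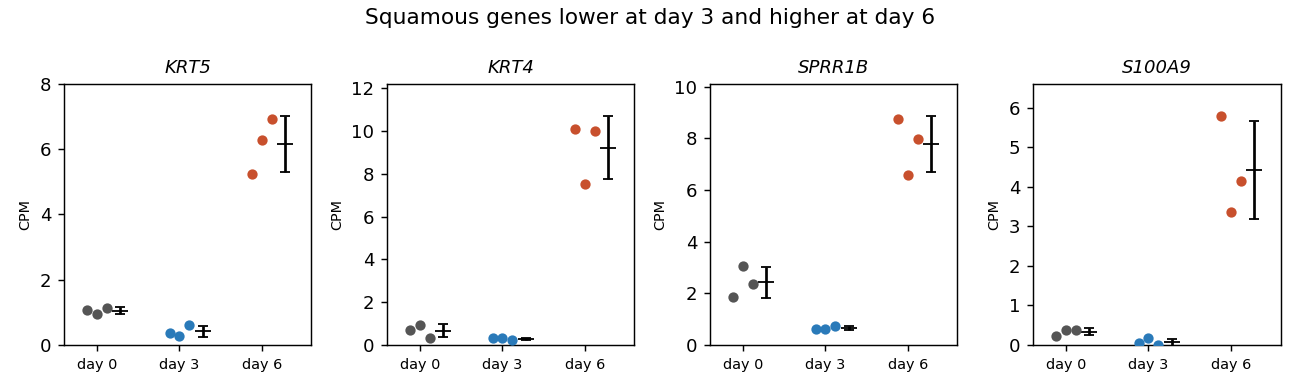
Level in CPM (vertical, linear from 0) of KRT5, KRT4, SPRR1B and S100A9 (chosen after its values were seen) on day 0, day 3 and day 6. Each point is 1 library, and the bar beside the points is the mean with its SD over n = 3. All 4 genes were lower on day 3 than on day 0 and highest on day 6, where KRT4 reached 9.23.

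TP63 did not change between day 3 and day 6 past the threshold (53 and 39 counts, log2 fold change -0.41, SE 0.46, adjusted p = 0.624), and SOX2 rose (log2 fold change 1.95, SE 0.26, adjusted p = 0.000253). HES1 rose (log2 fold change 1.35, SE 0.14, adjusted p = 5.71e-05). Among the largest rises were those of ZNF354B, FBLN1 (2.07 ± 0.674 to 22.7 ± 2.33), LSP1 (2.07 ± 0.33 to 19.9 ± 1.34), and CYFIP2 (2.35 ± 0.462 to 20.6 ± 0.797). KIF1A, FXYD5, FARP1 (10.7 ± 1.35 to 78.4 ± 4.31) and COL6A2 completed the 8 largest. ZNF354B varied within days, at 64.6 ± 83.7, 11.1 ± 0.57 and 140.1 ± 150 on day 0, day 3 and day 6 (adjusted p = 0.038). The largest falls were those of COL6A6 (24.7 ± 1.5 to 6.58 ± 0.366), CALML3, the kinase PAK3 (40.6 ± 1.8 to 14.4 ± 0.917), AVIL, IRS4 (156 ± 11.6 to 59 ± 6.2), GABRR3, SRGN (14.9 ± 0.0374 to 5.76 ± 0.494) and PLN.

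Tuft cell genes fell between day 3 and day 6, 6 of 13 with none higher (8 and 1 adjusted over the list alone). The list passed (camera, adjusted p = 0.000389, and adjusted p = 0.157 with an estimated correlation). The lineage factor POU2F3 went from 289 ± 5.92 to 228 ± 7.51, the cytoskeletal gene AVIL from 79.8 ± 2.65 to 29.4 ± 1.58, the cation channel gene TRPM5 from 13.2 ± 0.495 to 6.48 ± 0.737 and the kinase BMX from 128 ± 1.32 to 97.1 ± 4.81. Against day 0 this list passed on neither day (camera, adjusted p = 0.211 and 0.272), and SH2D6 was higher on both. Replication genes were lower again, 13 of 43 with none higher (23 and 0 adjusted over the list alone), and passed (camera, adjusted p = 4.8e-09, and adjusted p = 0.175 with an estimated correlation). The cell cycle factor gene E2F1 went from 87.7 ± 4.46 to 57 ± 5.02 and CCNE2 from 50.8 ± 4.01 to 36.3 ± 2.81. Of 43 mitosis genes only KIF20A passed, as higher, and none did adjusted over the list alone (camera, adjusted p = 0.95 for the list).

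From day 3 to day 6 genes of glycolysis and hypoxia rose, 15 of 30 with none lower (22 and 0 adjusted over the list alone). The list passed (camera, adjusted p = 2.27e-06, and adjusted p = 0.402 with an estimated correlation), with NDRG1 from 117 ± 9.35 to 389 ± 54.4, EGLN3 from 55.1 ± 2.29 to 121 ± 16.7 and VEGFA from 238 ± 17 to 337 ± 24.8. Cancer germline antigens rose, 8 of 16 with none lower (10 and 0 adjusted over the list alone). They passed (camera, adjusted p = 0.000389, and adjusted p = 0.212 with an estimated correlation), with SSX2 from 1.4 ± 1.25 to 9.52 ± 0.543. MHC class I genes rose, 8 of 17 with none lower (camera, adjusted p = 0.0136, and adjusted p = 0.306 with an estimated correlation). Mesenchymal genes rose, 10 of 24 with 2 lower (11 and 3 adjusted over the list alone), and passed (camera, adjusted p = 0.0136, and adjusted p = 0.17 with an estimated correlation). The actin-binding gene CALD1 had 433 counts against 27 (ratio 16.8, 11.4 to 25.8). Developmental transcription factors rose, 25 of 76 with 4 lower (28 and 8 adjusted over the list alone), and passed (camera, adjusted p = 0.0154, and adjusted p = 0.3 with an estimated correlation). LHX1 rose from 1.66 ± 0.388 to 7.33 ± 1.22 and OTX1 fell from 43.3 ± 0.503 to 26 ± 2.06.

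Further lists passed from day 3 to day 6 with fewer called members. Of 38 interferon response genes 3 rose (adjusted p = 0.0441, and adjusted p = 0.235 with an estimated correlation). Of 29 simple epithelial genes 6 rose (9, with 1 lower, adjusted over the list alone), and the list passed (adjusted p = 0.0441, and adjusted p = 0.49 with an estimated correlation). Of 15 gastric and intestinal genes 6 rose (6, with 2 lower, adjusted over the list alone), and this list passed too (adjusted p = 0.0303, and adjusted p = 0.219 with an estimated correlation). The TGF-beta and BMP list had 9 of 27 higher and 4 lower (12 and 4 adjusted over the list alone), with adjusted p = 0.0441, and adjusted p = 0.402 with an estimated correlation. NF-kB targets had 5 of 10 higher and 1 lower (6 and 1 adjusted over the list alone), with adjusted p = 0.023, and adjusted p = 0.235 with an estimated correlation. Of 15 heat shock genes 1 fell (adjusted p = 0.0123, and adjusted p = 0.402 with an estimated correlation).

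The cytosolic ribosomal protein list was higher on day 6 than on day 3 with no single member of 42 called (adjusted p = 0.0303, and adjusted p = 0.802 with an estimated correlation). Against day 0 its adjusted p was 0.058 on day 3 and 0.93 on day 6. The replication-dependent histone list was higher with 1 called member of 18 and none adjusted over the list alone (adjusted p = 0.0122, and adjusted p = 0.6 with an estimated correlation), after 0.0999 and 0.501 against day 0. Histone transcripts mostly lack poly-A tails, which limits their recovery from poly-A libraries. The lists of neuroendocrine (adjusted p = 0.0717), Notch (0.212), YAP (0.51), MHC class II (0.0861), WNT (0.0627), HOX (0.95), p53 target (0.958) and immediate early genes (0.0673) did not pass.

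In all, 1766 genes were higher and 731 lower on day 6 than on day 3 (D6 vs D3). Of these 970 and 69 had changed at least 2-fold. The libraries did not overlap for 2491 of the 2497 called genes and for 43.5% of all genes, against 10% by chance. D0_2 belongs to neither of these days, but leaving it out set the filter, the scaling and the shared estimate of the spread anew. Without it 2090 genes were lower and 55.4% of the called genes were higher, against 70.7% with all libraries. Without D3_1, D3_2, D3_3, D6_1, D6_2 and D6_3 the lower genes numbered 406, 348, 362, 448, 453 and 485.

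Of the 17 lists called between day 3 and day 6, 7 kept their call in all alternatives run for lists other than the estimated correlation (basal squamous, MHC class I, mesenchymal, tuft cell, DNA replication, cancer germline antigens and glycolysis and hypoxia). The TGF-beta and BMP pathway list lost it without each single library (up to 0.127), the interferon response list without any but D3_1 and D6_3 (up to 0.114) and the simple epithelial list without any but D0_2 and D6_2 (up to 0.147). The gastric and intestinal list lost it without D0_2, D3_2 or D6_3 (up to 0.0648), the cytosolic ribosomal proteins without D3_1, D3_2, D6_1 or D6_3 (up to 0.126) and the replication-dependent histones without D6_3 (0.127). Among genes with a mean of at least 5 CPM the squamous differentiation (0.308), developmental transcription factors (0.696), heat shock (0.0706) and NF-kB targets (0.056) lists lost theirs. So did the TGF-beta and BMP pathway and replication-dependent histone lists, and the median of the gastric and intestinal list turned to -0.20. With library size only the interferon response and TGF-beta and BMP pathway lists did. With fry the cytosolic ribosomal protein (adjusted p = 0.362) and replication-dependent histone (0.147) lists were not called.

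Day 3 and day 6 were also compared through their calls against day 0. Both comparisons called 5537 genes in the same direction, 3048 higher and 2489 lower. Independent lists of these sizes would share 997 and 713. The covariance of the log2 fold changes was 1.01, against 0.025 in 20 simulations of unchanged groups that shared the day 0 libraries. Those simulations gave no shared call. Part of the excess may come from the shared day 0 libraries, and 3 libraries cannot be split into groups of at least 2. Without D0_2, 5851 of the 6225 genes called on day 3 and 8024 of the 8380 called on day 6 were called again, all in the same direction. In the opposite direction 37 genes were called, among them KRT5, KRT4 and SPRR1B, which were lower on day 3 and higher on day 6 than on day 0. Most of the 37, PAK3 among them, were instead higher on day 3 and lower on day 6 than on day 0.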

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

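The tests of other cell types, of a swapped label, of depth, of GC content and length as the whole cause, of fewer cycling cells and of days in culture were chosen after the results were seen. The others were fixed before.

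Both comparisons with day 0 called 37 genes in opposite directions, and all 37 also passed the test between day 3 and day 6. Most of the 37, the kinase gene PAK3 among them, were higher on day 3 and lower on day 6 than on day 0. The members of gene lists among the 37 were mostly squamous genes that were lower on day 3 and higher on day 6. Their log2 fold changes from day 3 to day 6 were 5.81 (SE 0.71) for S100A9, 5.04 (SE 0.35) for KRT4, 3.91 (SE 0.28) for KRT5 and 3.59 (SE 0.24) for SPRR1B. The membrane repair gene MYOF had 2.11 (SE 0.18) and the calcium-binding gene S100A2 had 1.15 (SE 0.14). HHIP, which encodes a Hedgehog-binding protein, was higher on day 3 and lower on day 6 than on day 0, with -1.20 (SE 0.07). S100A9, VIM, SPARC, COL1A2 and COL3A1 were named after their values were seen. S100A9 and KRT4 were at 0.0682 and 0.272 CPM on day 3, near the floor.

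Changes of at least 2-fold went mostly upward, with 2289 genes higher and 119 lower on day 6 than on day 0. Scaling between libraries is argued against as the cause, since the share of higher genes was 94.7% with median-ratio scaling and 97% with library size only. Noise in genes with few counts on all days is argued against by a share of 92.3% among genes with a mean of at least 5 CPM. That mean is over all 9 libraries, so genes with few counts on day 0 alone stay in this set. COL6A2, with 4 counts on day 0 and 1367 on day 6, is 1 of them, and the share cannot speak to such genes. Cells of mesenchymal, endothelial or blood origin would bring VIM, which was at 0.22 CPM on day 6 beside 37.9 for COL6A1. SPARC (0.482), COL1A2 (0.502) and COL3A1 (0.105) were low too, but other list members such as FBLN1 (22.7) and COL1A1 (9.53) were not. Higher on day 6 than on day 0 were 14 of 24 mesenchymal, 5 of 6 fibroblast, 4 of 5 endothelial and 3 of 8 leukocyte genes tested. The low level of VIM therefore speaks only to cells that express it. A response of the cells to the inhibitor may account for the pattern and stays open as a hypothesis, together with days in culture, which the design does not separate from it.

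Library D0_2 stood apart from the other day 0 libraries, with a chi-square per degree of freedom of 55.36 and 47.61 against them and 4.94 between them. A label swapped with a later library is argued against, since its mean correlation with day 0 was above that with day 3 by 0.026. Lower depth is argued against, since its 26 (in units of 1e+06 counts) lay above the 21.6 of D0_3, which correlated better. GC content and length fitted 16.9% of the variance of its deviation, while the highest such share among the other libraries was 44.4%. The 16.9% lay between the bounds set in advance, so a part played by GC content and length stays open. As the whole cause they are argued against, since with the trend removed its deviation had 2.547 times the SD between the other day 0 libraries (0.322 and 0.126), and no biological explanation was tested.

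Replication genes were lower on day 6 than on day 0 while the mitosis list did not pass. The median log2 fold change of the replication list minus that of the mitosis list was -0.384. Fewer cycling cells would leave no such difference if they lowered both lists alike. The difference restates the pattern, and whether both lists would fall alike was not tested, so fewer cycling cells stay open. In each library the mean of the replication genes minus that of the mitosis genes was -0.271 to -0.377 on day 6 and -0.049 to 0.157 on day 0. With 0 libraries of untreated cells kept for 3 or 6 days among those analysed, the inhibitor and days in culture cannot be told apart here.

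Each comparison of 3 with 3 libraries has 10 splits, too few for a share under 0.05. In fits of the 6 libraries alone the real split called 5307, 7282 and 4331 genes for day 3 against day 0, day 6 against day 0 and day 6 against day 3. The highest of the other splits called 0 in each comparison, so that 1 of the 10 splits gave as many genes.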

How the results depend on the processing

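Removal of the GC and length trend was chosen after the data were seen, and the other alternatives before. Of the counts recomputed under an alternative, 153 stayed within 1.5 times the value reported and 33 did not. Of the recomputed fold changes of always-named genes 834 kept their direction and side of the threshold, 20 passed it anew, 22 lost it and 17 turned. Of the recomputed tests of called lists 726 kept their direction and side of the threshold, 196 lost the threshold and 2 turned. The direction is that given by the list test, not the sign of the median. The cause was not tested except where the alternative's own construction gives it, as with fewer genes tested or a stricter threshold.

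With an estimated correlation 0 lists passed in D3 vs D0, 0 in D6 vs D0 and 0 in D6 vs D3, and fry called 32 in D6 vs D0. Library size only gave 1825 lower genes in D3 vs D0. Among genes with a mean of at least 5 CPM the lists called were 11, 12 and 11, with 831 higher and 420 lower genes in D6 vs D3. A fit of only the days compared gave 1824 lower genes in D6 vs D3. At least 2-fold changes were 1408 higher and 59 lower, 2289 and 119, and 970 and 69. At an adjusted p under 0.01, D3 vs D0 had 1471 lower genes and D6 vs D3 had 1159 higher and 285 lower. With the GC and length trend removed D3 vs D0 had 12 lists and D6 vs D3 had 1130 lower genes.

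With single libraries left out, lower genes in D3 vs D0 ranged from 1846 (without D3_1) to 3370 (without D0_2), and lists from 12 (without D3_1 or D6_2, and 13 without D0_3) to 21. In D6 vs D3 lower genes ranged from 348 (without D3_2) to 2090 (without D0_2).

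Reversals concerned small changes that had not passed, except for 2 lists. The log2 fold change of REST in D6 vs D0 turned to 0.0534 with library size only and 0.0219 among genes of at least 5 CPM, and ranged from -0.1605 to 0.006 with libraries left out. In D6 vs D3 that of REST ranged from -0.0437 to 0.1292. That of NEUROD1 in D6 vs D3 was -3e-04 without a filter, -0.05 with limma-voom and -0.0116 with the replicate number as block, and ranged from -0.1947 to 0.2459. NEUROD1 in D6 vs D0 ranged from -0.3713 to 0.0695 and SYP from -0.0755 to 0.1759. With the GC and length trend removed SYP was at -0.1581 and INSM1 at -0.1526 in D6 vs D0, and MYC at -0.0944 in D3 vs D0. The median of the gastric and intestinal list in D6 vs D3 was -0.205 among genes of at least 5 CPM, and that of the mitosis list in D3 vs D0 was -0.001 with the trend removed.

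Replicate numbers did not pair the libraries clearly, since 4 of 9 same-numbered pairs correlated above 0.1 (r across genes from -0.161 to 0.297) and 1 of 9 libraries correlated best with its own number on both other days. With the number as block the calls were 3373 higher and 2740 lower in D3 vs D0, 4394 and 3911 in D6 vs D0, and 1643 and 650 in D6 vs D3, with 21, 21 and 13 lists. The neuroendocrine list in D3 vs D0 (adjusted p = 0.0533) and the interferon response, simple epithelial, gastric and intestinal, and TGF-beta and BMP pathway lists in D6 vs D3 (0.0528 each) were not called with the block. Depth sets the floor of 0.098 to 0.141 CPM per library, so changes of genes such as KRT14 were not detectable.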

Other observations

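The tests against matched random lists were fixed before the results were seen, and no test in this part was chosen afterwards. The tuft cell genes SOX9, PLCG2, GFI1B, IL17RB, CHAT and IL25, which belong to a list fixed before, and C11orf53, COLCA2, POU2AF1, RGS13, HTR3E and IRAG2, which do not, were chosen after their values were seen.

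Transcripts of the tuft cell lineage, a chemosensory epithelial type, were abundant before exposure. On day 0 the lineage factor POU2F3 was at 285 ± 7.11 CPM, SOX9 at 262.5 ± 16.5, the phospholipase gene PLCG2 at 212.1 ± 40.8 and the lipoxygenase gene ALOX5 at 146 ± 6.36 (SD, n = 3). GFI1B was at 55.8 ± 5.53 and IL17RB at 65.6 ± 3.19, while IL25 was listed at 0 and CHAT was at 0.08 ± 0.0422. Genes of the POU2F3 coactivator family were expressed as well, with COLCA2 at 117 ± 18.4, C11orf53 at 66.5 ± 6.11 and POU2AF1 at 38.9 ± 4.79. On day 3 they were at 128.1 ± 3.04, 68.5 ± 2.87 and 50.75 ± 1.46, which was higher than on day 0 for POU2AF1 alone (adjusted p = 0.00513). From day 3 to day 6 they fell to 96.5 ± 3.87, 49.7 ± 2.85 and 33 ± 1.44 (adjusted p = 0.0141, 0.00233 and 0.000479). RGS13 went from 96.8 ± 23.8 on day 0 to 75.2 ± 3.25 on day 3 and 53.2 ± 8.13 on day 6 (adjusted p against day 0 = 0.0763 and 0.000559). The serotonin receptor gene HTR3E rose from 22.2 ± 4.57 to 28.3 ± 1.24 on day 3 with overlapping libraries (adjusted p = 0.0438) and was at 13.1 ± 1.25 on day 6, lower than on day 0 (adjusted p = 0.000454). IRAG2 went from 506 ± 42.9 to 399.8 ± 12.5 and 345 ± 30.7 (adjusted p against day 0 = 0.00968 and 0.000259).

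Developmental transcription factors and basal squamous genes were compared with 10000 random lists of genes matched on the level in D0_1, with changes taken from D0_2 and D0_3. A general rise of genes with few counts could raise both medians on day 6. The median log2 fold change of the developmental transcription factors was 0.69, against 0.347 in the random lists, and lay at percentile 99.62. That of the basal squamous genes was 1.278, against 0.185, and lay at percentile 100. Such a rise is therefore argued against as the whole cause of either.

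HOX genes did not pass as a list, although HOXB9 rose from no counts. Of 36 tested HOX genes 31 were at or above 1 CPM in D0_1, with a median log2 fold change of 0.013 at percentile 32.58 of matched random lists. A high level before exposure may leave little to rise, which predicts a large rise of the other 5. Their median of 1.492 lay at percentile 57.79, within the bound set in advance against that explanation. With 5 genes the random lists span -0.057 to 3.335, so the test could hardly have come out otherwise and the question stays open.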
